A study of Mus musculus with 49 samples.

How the data were processed

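RNA was measured in 49 libraries of mouse cerebellum from SCA1 and WT animals. Per the submitters' processing notes, RNA was isolated with TRIzol, libraries were made with the Illumina TruSeq stranded total RNA kit, and reads were mapped to GRCm38 and analysed with edgeR in R 4.1.0. The aligner, the settings of the counting tool and the annotation release are not given in the sources used here. The deposited table gives, per the file headers, integer read counts per gene and library, for 55487 gene IDs. Its length column holds, per the file headers, the summed exon length in bases of each gene, which was not used here. Symbols and GRCm38 positions came from a reference annotation matched by Ensembl ID, with a symbol for 55141 IDs; IDs without one held 0.0466% of the counts, and 107 IDs that shared a symbol with another were shown by ID.

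Genotype, region and animal were taken from the labels. The animal comes from the number in each title, and libraries with the same number were taken as regions of the same animal. This pairing was checked on residual expression: pairs of cortical libraries of the same animal had a median correlation of 0.174 (36 pairs), and pairs from different animals -0.0494 (186 pairs). Pairs of a cortical and a deep nuclear library had medians of 0.0639 within animals (33 pairs, 12 over 0.1) and -0.00542 between animals (204 pairs). Animals are numbered here from 1 to 14; numbers 12, 13 and 14 are SCA1 animals whose original numbers are 73000 and above. Library totals ranged from 19.3 to 31.6 M counts, with a mean of 24.1 M and an SD of 2.26 M. The biological coefficient of variation was 0.149 in the anterior vermis, 0.123 in the posterior vermis, 0.101 in the hemisphere and 0.151 in the deep nuclei. No 2 libraries of a group were duplicates, the smallest chi-square per degree of freedom of a pair being 5.82.

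Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table, version 1.17.8. Libraries were scaled by TMM, genes were filtered with filterByExpr (minimum count 10), and quasi-likelihood F-tests with robust dispersion were adjusted by Benjamini-Hochberg at a false discovery rate of 0.05. The genotype effect, SCA1 minus WT, was tested in each region alone. Cortical regions were compared within each genotype by a test with 2 degrees of freedom and 3 pairwise contrasts, with animal as block. The interaction of genotype with cortical region used 36 libraries, and that of genotype with deep nuclei against the cortical mean 44 libraries of the 11 animals with all 4 regions, both with animal as block. Log2 CPM used a prior count of 2. Distances between regions were computed over the 500 genes with the largest variance within animals and compared by exact permutation of genotype over animals. These comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

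Lists of 17 cell types and 17 pathways, 478 genes in all with 27 in more than 1 list, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, which tests whether the genes move one way on balance. Each was adjusted over the lists of a region. The cell type lists were Purkinje, zebrin-positive Purkinje, zebrin-negative Purkinje and granule cells, molecular layer interneurons, Golgi and unipolar brush cells, deep nuclear neurons, Bergmann glia, astrocytes, microglia, myelin, oligodendrocyte precursors, choroid plexus, endothelium, pericytes, meninges and erythrocytes. The pathway lists were mGluR1 and calcium signalling, potassium and sodium channels, glutamate receptors, GABA and glycine transmission, synaptic vesicle and scaffold, reactive astrocyte, disease-associated microglia, interferon response, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, immediate early genes, heat shock and unfolded protein response, Capicua targets, perineuronal net, and neurotrophin, IGF and VEGF signalling. Members past the threshold were counted with adjustment over all genes and over the list alone.

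Named genes followed a rule. Atxn1 came first. For each genotype effect the rule took the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 3, leaving out provisional names, mitochondrial genes and sex-linked markers. It added up to 4 members of each list with the smallest p in a region, the 10 genes with the smallest p in each region or interaction test, and the 10 shared genes with the smallest maximum p. The text names a part of these. Pcp2, Calb1, Slc17a6, Ttr and Gabra6 are given as tissue markers.

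Alternatives were DESeq2, its size factors in edgeR, library size alone, no low-count filter, a filter at 1 CPM, limma-voom with quality weights, a false discovery rate of 0.1, a fold change of at least 1.5, no animals numbered 73000 and above, the number series or Xist as a covariate, all regions in one fit, no block, SCA1 matched to 5 animals, and each animal left out in turn. Distances were also taken over 2000 genes, over all genes, with a prior count of 5, as a projection, and without choroid, meninges and erythrocyte genes and the 100 genes most correlated with Ttr. Covariates from Slc17a6, Ttr and Gabra6, and distances without nuclear genes, were chosen after seeing the data. Groupings by chance were judged by fits to other divisions of the same animals, 100 at most. For both interaction results the number of divisions was lowered to 60, for computing time, after a larger drawing had been seen. The fits were tested on simulated data with 200 changed genes: in the anterior vermis, posterior vermis, hemisphere and deep nuclei 84%, 92%, 90.0% and 90.0% of 2-fold changes and 54%, 66%, 76% and 56% of 1.5-fold changes were called, and 3.91%, 2.92%, 2.8% and 3.85% of calls were false. For the region test in WT 6.98% of calls were false, and for the interaction with cortical region 2.07%. The simulated genes varied independently of one another, without the differences in tissue between dissections that many genes share. These rates therefore need not hold in the real libraries.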

Results

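RNA was measured by sequencing in the cerebellum of mice with spinocerebellar ataxia type 1 (SCA1) and of wild-type (WT) mice. SCA1 is a neurodegenerative disease caused by an expanded glutamine tract in ataxin 1. The 49 libraries came from 14 animals, 6 WT and 8 SCA1, and from 4 dissected regions. These were the anterior vermis, posterior vermis and hemisphere of the cerebellar cortex, and the deep nuclei, which carry the output of the cerebellum. Each cortical region had 5 WT and 7 SCA1 libraries, the deep nuclei had 6 WT and 7 SCA1 libraries, and 11 animals had all 4 regions. Counts assigned to genes ranged from 19.3 to 31.6 M per library, and the means of the 8 groups from 22.8 to 25.0 M. The labels gave no age, sex or mouse line. Xist was high in 4 of the 6 WT and 3 of the 8 SCA1 animals, and Y-linked genes in the others. Expression is given as CPM, counts scaled to library size by TMM, with the SD over animals, and differences as log2 fold changes of SCA1 against WT with the SE. Unless stated otherwise, n is 5 WT and 7 SCA1 animals in a cortical region, and 6 WT and 7 SCA1 in the deep nuclei.

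Atxn1, the gene mutated in the disease (ENSMUSG00000046876, GRCm38 chromosome 13, 45549755 to 45965008, minus strand), was read in every library with 894 to 2210 counts. Its RNA rose in SCA1 anterior vermis from 60.4 ± 7.92 to 75.1 ± 7.49 CPM, a log2 fold change of 0.31 ± 0.09 (adjusted p = 0.0191). It rose in the posterior vermis from 62.8 ± 7.95 to 75.3 ± 5.80 CPM (0.26 ± 0.07, adjusted p = 0.0184). In the hemisphere it was 61.1 ± 7.93 in WT and 70.4 ± 5.19 CPM in SCA1 (adjusted p = 0.0533). In the deep nuclei it was 49.4 ± 7.88 and 58.6 ± 4.76 CPM (adjusted p = 0.121). Neither passed the threshold. The genotypes overlapped in each region, in the anterior vermis with a highest WT value of 72.5 and a lowest SCA1 value of 63.3 CPM. Total Atxn1 RNA did not check the label of a single library. The call for Atxn1 anterior vermis RNA ended without WT animal 2 (adjusted p = 0.057) or WT animal 10 (0.0557), and that for Atxn1 posterior vermis RNA without WT animal 7 (0.0509).

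The first question was which genes SCA1 changed in each region. Losses recurred from region to region: among genes with a mean log2 CPM of at least 3, Igfbp5, Plk5, Il20rb, Mirt1 and Clstn2 were among the 10 strongest falls in each cortical region. Onecut2, Slc44a5, Synpr and Fam163b rose in all 4 regions. By the edgeR quasi-likelihood F-test at a Benjamini-Hochberg false discovery rate of 0.05, 3237 of 17082 tested genes differed in the anterior vermis, 3330 of 16980 in the posterior vermis, 3422 of 16866 in the hemisphere and 1291 of 17173 in the deep nuclei. Most changes were small, with a median absolute log2 fold change of the called genes of 0.33 in the anterior and posterior vermis, 0.30 in the hemisphere and 0.37 in the deep nuclei. Among genes changed at least 2-fold, falls outnumbered rises: 190 against 68 in the anterior vermis, 184 against 105 in the posterior vermis, 150 against 78 in the hemisphere and 86 against 49 in the deep nuclei. The 2 genotypes did not overlap for 1576, 1777, 1778 and 583 genes in these regions. These were 9.23%, 10.5%, 10.5% and 3.39% of the genes tested, where chance gives 0.253% in a cortical region and 0.117% in the deep nuclei. With scaling by library size alone the share of called genes that were higher moved from 44.5% to 64.9% in the posterior vermis, from 43.8% to 64.6% in the hemisphere and from 39.3% to 64.8% in the deep nuclei.

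**Figure D1:**
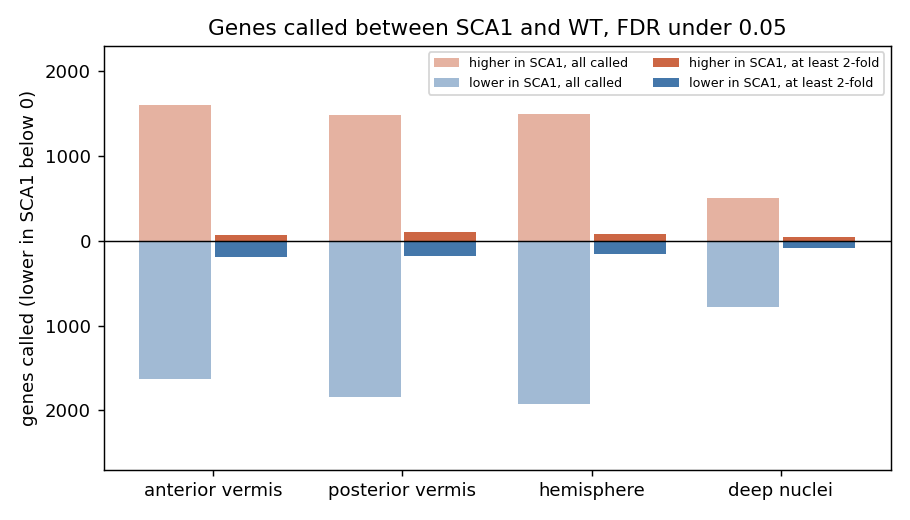
Number of genes that differed between SCA1 and WT in each region (horizontal axis), with genes higher in SCA1 drawn upward and genes lower drawn downward (vertical axis, number of genes); the bars of each region are all genes at a false discovery rate of 0.05 and those changed at least 2-fold. The 3 cortical regions held 3237 to 3422 called genes and the deep nuclei 1291.

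In SCA1 anterior vermis, RNA of Igfbp5, a secreted protein that binds insulin-like growth factors (ENSMUSG00000026185, chromosome 1, 72857932 to 72874884), fell from 291 ± 45.7 to 67.0 ± 8.19 CPM, a log2 fold change of -2.12 ± 0.11 (adjusted p = 6.15e-08). Rasal1, a Ras GTPase-activating protein, fell by 2.18 ± 0.14 from 16.1 to 3.54 CPM, and the polo-like kinase gene Plk5 by 2.02 ± 0.18 from 78.1 to 19.2 CPM. Clstn2, which encodes a postsynaptic membrane protein, fell from 76.6 ± 15.3 to 23.7 ± 3.71 CPM (-1.70 ± 0.13, adjusted p = 3.79e-06). The histamine receptor gene Hrh3 fell by 1.49 ± 0.14. Genes that rose included the choline transporter-like gene Slc44a5 (1.78 ± 0.18) and the homeodomain transcription factor gene Onecut2 (1.78 ± 0.14, ENSMUSG00000045991, chromosome 18, 64340020 to 64400987), which went from 9.14 ± 1.83 to 31.4 ± 4.75 CPM (adjusted p = 1.96e-06). Synpr, a synaptic vesicle membrane protein gene, rose from 51.7 ± 9.07 to 125.2 ± 13.2 CPM (1.28 ± 0.11, adjusted p = 4.43e-06). The potassium channel gene Kcnb2 rose by 1.21 ± 0.19 and Eif2ak2, a kinase activated by double-stranded RNA, by 1.09 ± 0.11. Slc17a6, the glutamate transporter of deep nuclear neurons, stood at 77.2 ± 45.2 CPM in WT and 27.4 ± 27.3 CPM in SCA1 anterior vermis, with overlapping ranges (33.9 to 132.2 and 3.96 to 76.5 CPM). The choroid plexus gene Ttr stood at 1517 ± 2024 and 2929 ± 2669 CPM, with ranges of 18.8 to 4183 and 53.9 to 6592 CPM. With log2 CPM of Slc17a6 and Ttr as covariates, an alternative chosen after seeing the data, 1494 genes were called in place of 3237. The count was 2015 without the SCA1 animals numbered 73000 and above.

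In SCA1 posterior vermis, Th, the rate-limiting enzyme of catecholamine synthesis, fell from 27.8 ± 4.83 to 5.28 ± 1.82 CPM (-2.39 ± 0.24, adjusted p = 3.23e-05). Igfbp5 fell from 221.3 ± 14.8 to 56.5 ± 11.3 CPM (-1.97 ± 0.12) and Clstn2 from 95.5 ± 7.04 to 29.97 ± 2.22 CPM (-1.67 ± 0.06, adjusted p = 1.12e-11). Unc13d, a regulator of vesicle exocytosis, fell by 2.25 ± 0.12, and Mdfi, an inhibitor of myogenic transcription factors, by 2.32 ± 0.12. Fam163b (ENSMUSG00000009216, chromosome 2, 27110380 to 27142491) rose from 12.5 ± 2.22 to 59.3 ± 6.40 CPM (2.25 ± 0.11, adjusted p = 5.20e-09). Onecut2 rose from 5.60 ± 1.98 to 26.3 ± 3.86 CPM (2.23 ± 0.18), and Sfrp4, a secreted Wnt antagonist, by 1.86 ± 0.12. The pro-apoptotic gene Hrk rose from 8.70 ± 1.56 to 30.4 ± 6.58 CPM (1.80 ± 0.17, adjusted p = 8.39e-06). Necab1, a neuronal calcium-binding protein gene, rose by 1.20 ± 0.07 and Synpr by 1.26 ± 0.10. Slc17a6 was at 8.03 ± 6.10 CPM in WT and 17.02 ± 30.3 CPM in SCA1, where animal 13 alone reached 85.6 CPM. Ttr was at 1823 ± 1600 CPM in WT and 651.8 ± 1101 CPM in SCA1, with medians of 1476 and 12.3 CPM.

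In SCA1 hemisphere, strong falls included Igfbp5 (-1.96 ± 0.09) and Grm4, the presynaptic glutamate receptor of granule cell axons (ENSMUSG00000063239, chromosome 17, 27422387 to 27521403). Grm4 RNA fell from 552 ± 54.5 to 181.1 ± 16.95 CPM (-1.61 ± 0.07, adjusted p = 2.29e-10). Plk5 fell by 1.96 ± 0.10, the long noncoding RNA Mirt1 by 2.18 ± 0.13, Clstn2 by 1.75 ± 0.07, and Dusp5, a phosphatase of the kinase ERK, by 1.57 ± 0.14. Fam163b rose from 11.7 ± 6.32 to 52.5 ± 7.18 CPM (2.17 ± 0.29, adjusted p = 0.000358) and Onecut2 by 1.93 ± 0.13. Synpr rose from 67.7 ± 5.69 to 172.8 ± 8.91 CPM (1.35 ± 0.05, adjusted p = 1.11e-11). The interferon-activated gene Ifi203 rose from 4.34 ± 1.08 to 12.8 ± 2.17 CPM (1.56 ± 0.16), and Hrk by 1.38 ± 0.18. Slc17a6 was at 26.7 ± 21.2 CPM in WT and 19.9 ± 14.4 CPM in SCA1, and Ttr at 395.6 ± 496.2 and 541.9 ± 387.8 CPM.

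In SCA1 deep nuclei, Igfbp5 fell from 180.2 ± 18.3 to 53.4 ± 1.66 CPM (-1.76 ± 0.06, adjusted p = 1.24e-10) and Grm4 from 284.9 ± 63.7 to 90.8 ± 24.1 CPM (-1.65 ± 0.19). Cd24a, a cell-surface glycoprotein gene, fell from 52.2 ± 24.0 to 10.1 ± 3.33 CPM (-2.38 ± 0.29, adjusted p = 0.000314). The collagen gene Col5a1 fell by 1.53 ± 0.25. Fam163b rose by 1.67 ± 0.09. Interferon-induced genes rose as well, with the largest list means in SCA1 animals 13 and 14. Without these 2 animals the median log2 fold change of the interferon response list went from 1.13 to 0.67. Ifit1 went from 4.90 ± 2.03 to 14.7 ± 8.58 CPM (1.58 ± 0.36, adjusted p = 0.0176). Irf7 rose from 4.90 ± 1.11 to 13.9 ± 6.84 CPM (1.497 ± 0.30), and Oasl2 from 8.44 ± 2.43 to 22.5 ± 13.4 CPM (1.41 ± 0.33), with 49.8 CPM in animal 13 and at most 28.4 CPM in the others. Granule cell and choroid RNA varied between dissections, with Gabra6 from 211.5 to 505.7 CPM in SCA1 and from 332.3 to 511.3 CPM in WT, and Ttr up to 7939 CPM. The count of 1291 genes was 674 with the animal number series as a covariate, 776 without WT animal 9 and 841 without WT animal 5. With covariates chosen after seeing the data it was 2479 (Slc17a6 and Ttr) and 2123 (Gabra6 and Ttr).

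**Figure D2:**
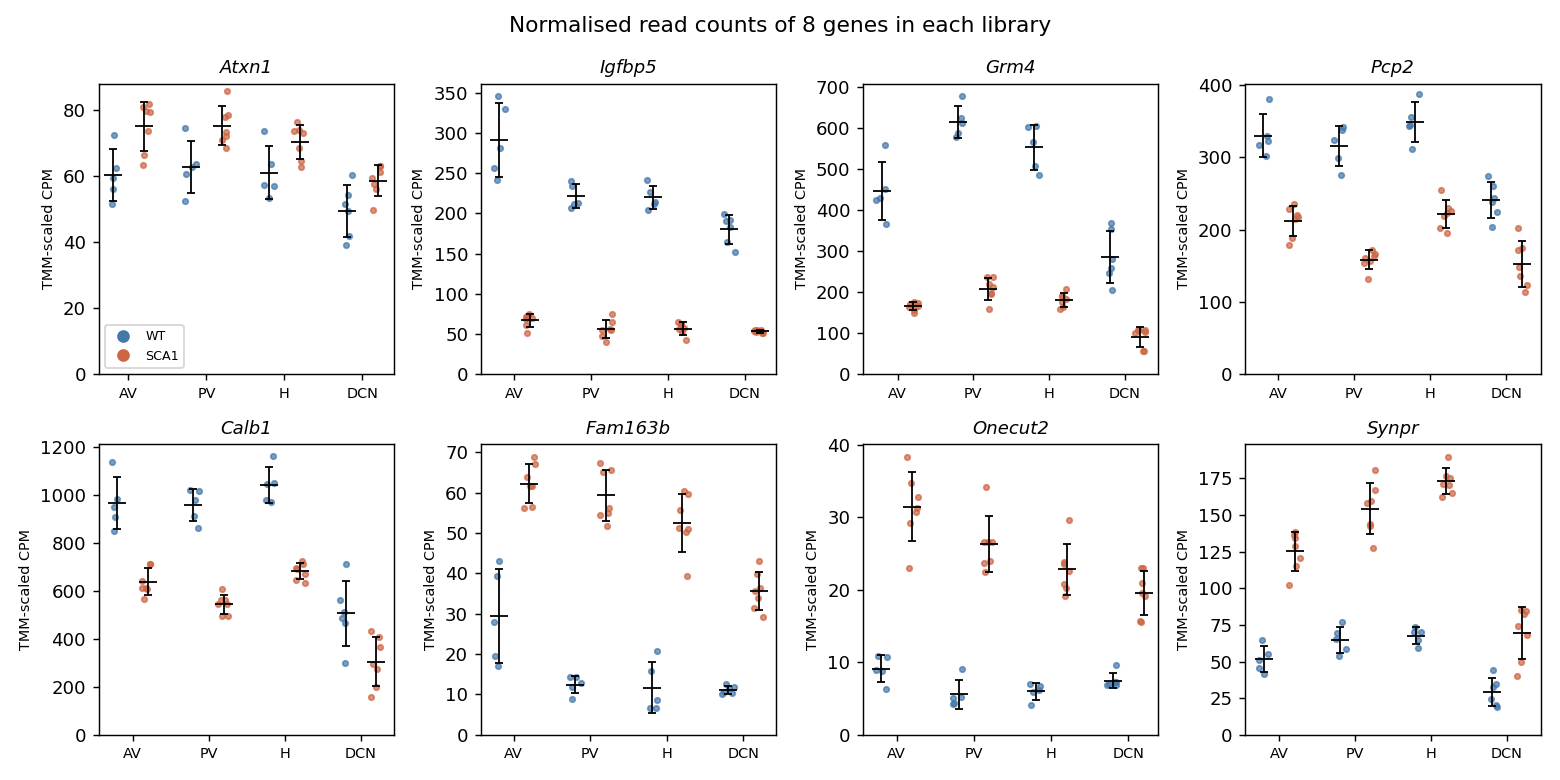
CPM (vertical axes) of Atxn1, Igfbp5, Grm4, Pcp2, Calb1, Fam163b, Onecut2 and Synpr in each library (points) by region and genotype (horizontal axes), with the mean and SD of each group. Igfbp5 fell from 291 to 67.0 CPM and Onecut2 rose from 9.14 to 31.4 CPM in the anterior vermis, while the Atxn1 ranges of the genotypes overlapped.

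Purkinje cells, the output neurons of the cortex, lost marker RNA in each region. All 16 genes of the Purkinje cell list were called lower in each cortical region, with a median log2 fold change of -0.66 in the anterior vermis, -0.91 in the posterior vermis and -0.68 in the hemisphere. In the deep nuclei 10 of 16 were lower (median -0.72), and 16 adjusted over the list alone. Cortical RNA varied between these dissections. In SCA1 animals 11 and 13 Calb1 was lowest, 197.6 and 159.3 CPM, and so was the granule cell gene Gabra6, 211.5 and 226.7 CPM. Pcp2 went from 315.6 ± 28.0 to 158.2 ± 12.9 CPM and the calcium buffer gene Calb1 from 957.5 ± 67.9 to 543.9 ± 39.8 CPM in the posterior vermis. Gng13, a G protein subunit gene, fell by 1.21 ± 0.08 in the anterior vermis. Rgs8 fell by 1.05 ± 0.05 in the hemisphere, from 1759 to 850.1 CPM. Lists were called by camera, a test of a list against all other genes. It gave the Purkinje cell list adjusted p values of 2.9e-20, 5.06e-27, 1.76e-23 and 9.63e-14 in the anterior vermis, posterior vermis, hemisphere and deep nuclei with the preset correlation. With an estimated correlation they were adjusted p = 0.0709, 0.0481, 0.0669 and 0.249. Genes of zebrin-positive Purkinje cells, the stripes that express Aldoc, were called lower for 5, 6, 6 and 3 of 7 members, with medians of -0.43, -1.04, -0.73 and -0.44 in the same order (adjusted p = 0.0303, 0.0481, 0.0144 and 0.0684 with an estimated correlation). The 4 zebrin-negative genes had 3, 3, 3 and 2 members lower, with medians of -0.42, -0.41, -0.37 and -0.35 (adjusted p = 0.122, 0.181, 0.0669 and 0.197 with an estimated correlation). Of these 4 genes Nefh is also in the deep nuclear neuron list. The WT zebrin-negative mean was 6.72 log2 CPM in the nuclei and 6.39 in the posterior vermis, while the Purkinje cell list had 7.65 and 8.48. The zebrin-negative list thus did not read Purkinje cells alone.

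Genes of mGluR1 and calcium signalling, many of them Purkinje cell genes, were lower for 13, 16, 14 and 9 of 17 members in the anterior vermis, posterior vermis, hemisphere and deep nuclei (13, 16, 15 and 15 adjusted over the list alone). Itpka, an inositol phosphate kinase gene, fell by 1.12 ± 0.08 in the posterior vermis, and the scaffold gene Homer3 by 0.72 ± 0.05 in the hemisphere. The list was called lower in each region (camera adjusted p = 8.47e-11 or smaller), but not with an estimated correlation (adjusted p = 0.158, 0.0535, 0.0897 and 0.261). Among potassium and sodium channels 11, 11, 13 and 9 of 21 were lower, and 1 higher in the anterior vermis. The sodium channel subunit gene Scn4b fell by 0.70 ± 0.06 in the anterior vermis. This list was called lower in the 4 regions, with adjusted p = 0.183, 0.0788, 0.00748 and 0.0478 with an estimated correlation. Glutamate receptors were lower for 7, 9, 9 and 3 of 20 members and higher for 2 in each cortical region, with Grm4 among those lower in each. The kainate receptor gene Grik1 fell by 0.73 ± 0.07 in the posterior vermis. This list was called lower in each region, with adjusted p = 0.348, 0.226, 0.145 and 0.275 with an estimated correlation. GABA and glycine transmission genes were lower for 7, 5, 7 and 5 of 22 members, with the receptor gene Gabbr2 falling by 0.59 ± 0.04 in the posterior vermis. The list was called lower in each region (adjusted p = 0.246, 0.476, 0.145 and 0.249 with an estimated correlation). Its median in the posterior vermis was -0.03, and 0.02 with library size alone.

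Astrocyte and Bergmann glia RNA was lower too. In the anterior vermis 9 of 10 astrocyte genes fell (10 adjusted over the list alone, median -0.36), among them the gap junction gene Gja1 (-0.42 ± 0.05) and Agt (-0.69 ± 0.09). Camera called the astrocyte list there with both the preset and an estimated correlation (adjusted p = 1.93e-07 and 0.00919). In the posterior vermis, hemisphere and deep nuclei 7, 7 and 4 astrocyte genes were lower, and the list was called lower (adjusted p = 0.111, 0.121 and 0.0876 with an estimated correlation). Of 8 Bergmann glia genes 6, 7, 7 and 4 were lower in the 4 regions (adjusted p = 0.102, 0.0481, 0.0897 and 0.0831 with an estimated correlation). Gdf10 fell from 216.5 to 113.3 CPM (-0.93 ± 0.08) in the posterior vermis. Myelin genes were lower for 13 of 16 members in the anterior vermis and for 4, 2 and 1 members in the posterior vermis, hemisphere and deep nuclei. Camera called the myelin list lower in each region, with adjusted p = 0.19, 0.476, 0.577 and 0.607 with an estimated correlation. In the anterior vermis 5 of 9 deep nuclear neuron genes were lower as well, such as Nefh (-0.37 ± 0.08), with camera adjusted p = 0.00111 and adjusted p = 0.246 with an estimated correlation. Camera did not call that list in the other regions. Myelin and astrocyte RNA was higher in nuclei. WT list means were 8.52 and 7.745 log2 CPM there and 6.52 and 7.386 in the anterior vermis. Genes at least 2-fold higher in WT nuclei than in cortex had a median of -0.163 in the anterior vermis, 164 lower and 26 higher. In the posterior vermis the median was 0.0292, with 65 lower and 82 higher. Less nuclear tissue in the SCA1 anterior vermis dissections was not told apart from the falls of these lists there. Granule cell genes were lower for 2, 7, 7 and 1 of 12 members, with Cbln1 falling by 0.48 ± 0.06 in the hemisphere. The granule cell list was called lower in the posterior vermis, hemisphere and deep nuclei (adjusted p = 0.382, 0.229 and 0.573 with an estimated correlation). Eomes, the transcription factor of unipolar brush cells, fell by 1.62 ± 0.30 in the posterior vermis and 2.07 ± 0.33 in the deep nuclei. Camera did not call the Golgi and unipolar brush cell list of 5 genes in any region, while fry called it lower in the posterior vermis and deep nuclei (adjusted p = 0.0172 and 0.0014).

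**Figure D3:**
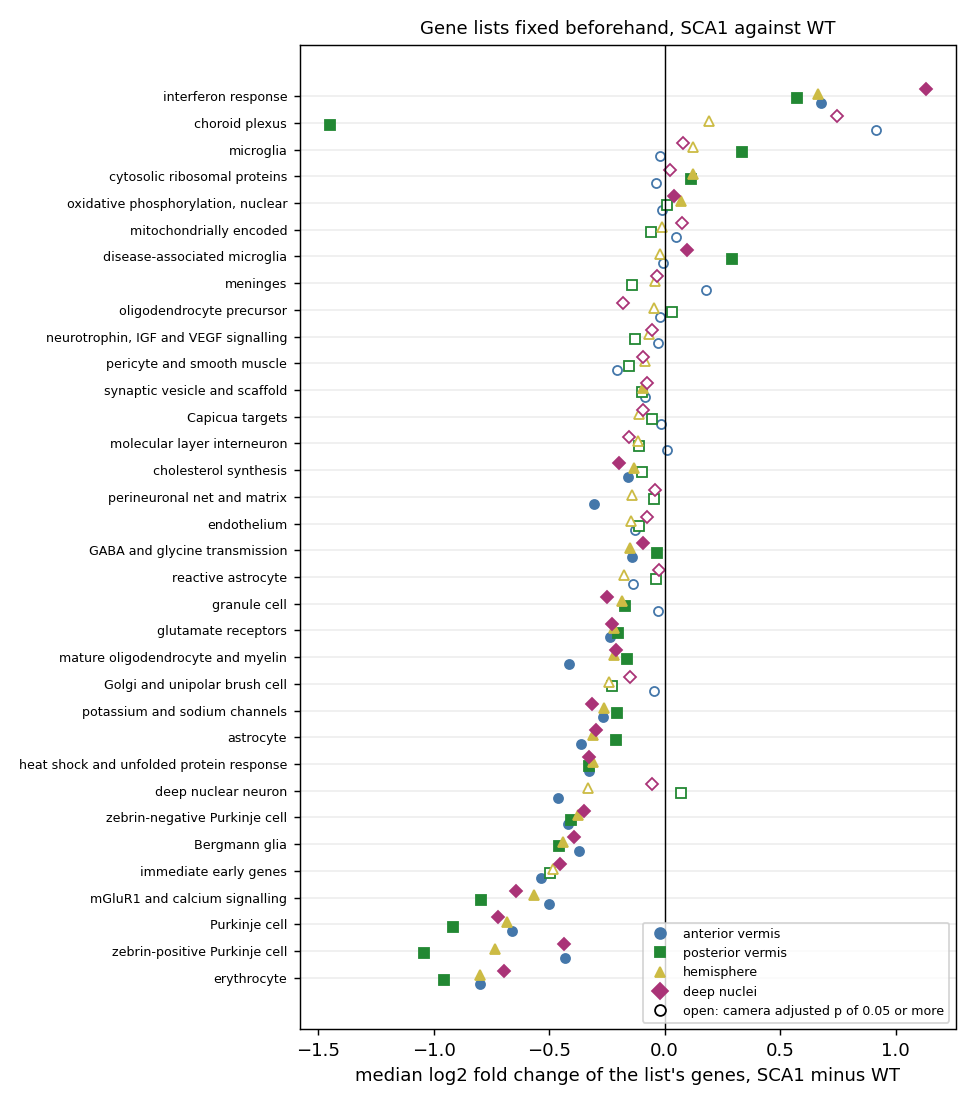
Median log2 fold change (SCA1 minus WT, horizontal axis) of each gene list (vertical axis) in the 4 regions (points), with open points where camera gave an adjusted p of 0.05 or more. Purkinje cell genes lay between -0.66 and -0.91, and interferon response genes between 0.58 and 1.13.

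Interferon response genes rose in each region. Of the members tested 7 of 11 rose in the anterior vermis, 8 of 12 in the posterior vermis, 7 of 11 in the hemisphere and 8 of 12 in the deep nuclei (10, 8, 8 and 12 adjusted over the list alone). The medians were 0.68, 0.58, 0.66 and 1.13. Without SCA1 animals 13 and 14, those numbered 73000 and above, the deep nuclei median was 0.67, with 5 members called. Their list means there were 3.78 log2 CPM or more, against 2.45 to 3.27 in the other SCA1 animals. The transcription factor gene Irf7 rose by 1.45 ± 0.17 in the anterior vermis. The mean log2 CPM of the list was higher in each of the 7 SCA1 animals than in any WT animal in every cortical region, and in 5 of 7 in the deep nuclei. Exact permutation tests over animals, with both tails counted, gave p = 0.00253, 0.00126, 0.00126 and 0.0035, of which 0.00126 is the smallest the cortical design allows. Camera adjusted p values were 7.75e-07, 9.46e-07, 4.78e-07 and 1.5e-09, with adjusted p = 0.183, 0.193, 0.145 and 0.249 with an estimated correlation. Microglia genes rose for 8 of 15 members in the posterior vermis (9 adjusted over the list alone), among them Ctss (0.62 ± 0.06) and the complement gene C1qa (0.47 ± 0.08). The library of SCA1 animal 13 stood apart there, with a microglia list mean of 3.45 log2 CPM (nearest 3.23) and a deep nuclear neuron list mean of 5.02 (nearest 3.78). Camera gave an adjusted p = 2.58e-06 and adjusted p = 0.111 with an estimated correlation. Camera did not call the microglia list in the anterior vermis, hemisphere or deep nuclei, where 0, 1 and 0 members rose. Disease-associated microglia genes, such as the lectin gene Clec7a (1.38 ± 0.27), rose for 6 of 11 members in the posterior vermis (camera adjusted p = 0.013, and adjusted p = 0.224 with an estimated correlation). In the deep nuclei 2 of 13 rose (camera adjusted p = 0.0306, and adjusted p = 0.573 with an estimated correlation). Blood differed with genotype: haemoglobin and other erythrocyte genes were lower for 5, 5, 3 and 4 of 5 members in the 4 regions, with medians of -0.80, -0.96, -0.80 and -0.70 (adjusted p = 0.214, 0.224, 0.395 and 0.261 with an estimated correlation).

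**Figure D4:**
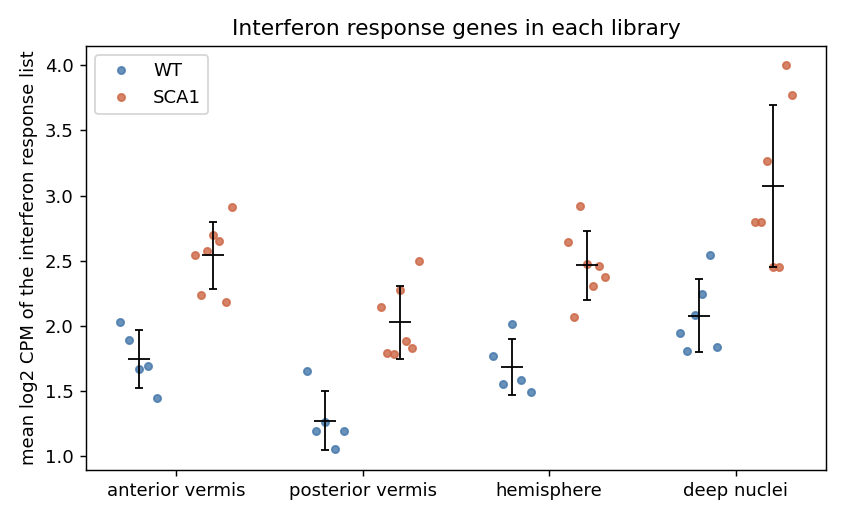
Mean log2 CPM of the interferon response list (vertical axis) in each library (points), by region and genotype (horizontal axis), with the mean and SD of each group. The group means rose from 1.75 to 2.54 in the anterior vermis and from 2.08 to 3.08 in the deep nuclei.

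The next comparison asked which changes the regions shared. Myo15, an unconventional myosin gene, fell in all 4 regions, with log2 fold changes of -4.30 ± 0.17, -4.39 ± 0.28, -4.18 ± 0.17 and -3.69 ± 0.22 in the anterior vermis, posterior vermis, hemisphere and deep nuclei. In the anterior vermis it went from 11.9 ± 2.33 to 0.599 ± 0.16 CPM (ENSMUSG00000042678, chromosome 11, 60469339 to 60528369). The axon guidance gene Sema7a fell by 0.87 ± 0.06, 0.90 ± 0.06, 0.86 ± 0.04 and 0.71 ± 0.06. Kcnip4, a potassium channel partner, fell by 0.65 ± 0.06, 0.83 ± 0.05, 0.66 ± 0.04 and 0.77 ± 0.06. Polr2a, the largest subunit of RNA polymerase II, rose by 0.69 ± 0.07, 0.63 ± 0.06, 0.58 ± 0.05 and 0.63 ± 0.04. Of 16365 genes tested in each region, 3068 were called in the same direction in 2 or more regions, 1386 higher and 1682 lower; 779 were called in all 4, of which 510 were lower. Opposite calls occurred for 2 genes. The deep nuclei libraries also held RNA of cortical cells. In WT, Gabra6 was at 420.9 CPM there and 688.8 CPM in the posterior vermis, and Pcp2 at 240.9 and 315.6 CPM. Calls shared with the deep nuclei may in part read cortical tissue in these dissections, which was not tested. Across genes, which are not independent replicates, log2 fold changes of region pairs correlated with Pearson r from 0.535 for anterior with posterior vermis to 0.761 for posterior vermis with hemisphere. When the regions of a pair were taken from different animals, with fewer animals on each side, the median r was 0.353 to 0.538. Covariances, which added noise does not shrink, were 0.0427 to 0.0665, against 0.0576 to 0.0779 over all animals. With genotype permuted over the 11 animals with all regions, the median r was 0.185 to 0.317 and the median covariance 0.00545 to 0.0102. There both regions came from the same animals. The highest permuted r exceeded the real one in these 11 animals for anterior with posterior vermis (highest 0.664), anterior vermis with deep nuclei (0.613 against 0.59) and posterior vermis with hemisphere (0.788 against 0.75).

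Within each genotype, cortical regions were then compared within animals. In WT, the transcription factor gene Nr2f1 (ENSMUSG00000069171) was higher in the hemisphere than in the anterior vermis by 0.997 ± 0.07 and than in the posterior vermis by 1.02 ± 0.07 (n = 5). In SCA1 it was higher by 0.97 ± 0.04 and 1.07 ± 0.04 (n = 7). Mdga1, a synaptic adhesion gene, was 0.92 ± 0.07 higher in WT posterior than anterior vermis, and Inhbb, an activin subunit gene, 1.48 ± 0.11 higher. The axonemal dynein genes Dnah10 and Dnah1 were lower in WT posterior than anterior vermis, with differences of -2.82 ± 0.22 and -2.20 ± 0.18, and the adenylate kinase gene Ak7 differed by -2.36 ± 0.20. The WT dissections also differed in other tissue, with Slc17a6 at 77.2 CPM in the anterior and 8.03 CPM in the posterior vermis. Tissue taken with the anterior vermis was not told apart from expression of the cortex itself. In SCA1, Nfatc2 was 0.81 ± 0.05 higher in the hemisphere than in the anterior vermis, and Car8, a Purkinje cell gene, differed by -0.45 ± 0.04 between posterior and anterior vermis. Any difference among the 3 regions was called for 3204 of 17271 genes in WT and 3910 of 17234 in SCA1. The WT pairs gave 2746 genes for posterior against anterior vermis, 1937 for hemisphere against anterior vermis and 763 for hemisphere against posterior vermis. The SCA1 pairs gave 1881, 2391 and 2256. SCA1 had more animals, and over the 21 choices of 5 of the 7 the median was 1656 genes, with a range of 867 to 5428 that holds the WT count. Single animals moved these counts: WT gave 1732, 1961, 2109 and 1482 genes without animals 2, 3, 5 and 7, and SCA1 gave 2075, 2328 and 2510 without animals 4, 6 and 8, and 5367 without animal 13. With Slc17a6 and Ttr as covariates, chosen after seeing the data, WT gave 842 and SCA1 3840.

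Whether cortical regions lay closer together in SCA1 was tested with 1 value per animal, the root mean square log2 CPM difference between regions over the 500 most variable genes. It was 1.98 ± 0.27 (SD, n = 5) in WT and 1.92 ± 0.34 (SD, n = 7) in SCA1, and the genotypes were not told apart (difference -0.06, two-sided exact permutation p = 0.742, smallest possible 0.00126). The sign of the difference was not stable: it was 0.0727 without animals numbered 73000 and above, 0.0219 without WT animal 3 and 0.0283 without SCA1 animal 12. Of the 500 genes 117 differed 2-fold between nuclei and cortex, and 82 were choroid, meninges or erythrocyte genes or among the 100 most correlated with Ttr. Without those of choroid, meninges, erythrocytes and Ttr the difference was -0.138 (exact permutation p = 0.287). Between deep nuclei and cortex the value was 1.997 ± 0.46 (SD, n = 5) in WT and 2.08 ± 0.23 (SD, n = 6) in SCA1, a difference of 0.08 (two-sided exact permutation p = 0.703, smallest possible 0.00216). This sign turned as well, to -0.0848 without WT animal 2 and -0.0125 without WT animal 3. Aldoc, the zebrin gene, was an example chosen after its values were seen: it was 0.76 ± 0.07 higher in posterior than anterior vermis in WT and 0.25 ± 0.04 in SCA1.

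The effect of SCA1 itself differed between posterior and anterior vermis for a small set of genes. Aldoc (ENSMUSG00000017390, chromosome 11, 78322968 to 78327781) fell by 0.65 ± 0.07 in the anterior and 1.18 ± 0.06 in the posterior vermis, where it went from 2595 ± 254.9 to 1144 ± 69.3 CPM. The difference of the effects was -0.51 ± 0.08 (adjusted p = 0.00153). Car9, a carbonic anhydrase gene, fell by 2.58 ± 0.19 in the anterior and 3.95 ± 0.19 in the posterior vermis (difference -1.38 ± 0.23, adjusted p = 0.00319). The zinc finger gene Zfp92 rose by 2.64 ± 0.18 in the posterior vermis, from 1.07 ± 0.28 to 6.65 ± 1.13 CPM. It had a log2 fold change of 0.29 ± 0.22 in the anterior vermis (adjusted p = 0.397), with a difference of 2.38 ± 0.25 (adjusted p = 2.88e-06). The cell cycle gene Rprm rose by 2.56 ± 0.18 in the posterior vermis, with 0.41 ± 0.20 in the anterior vermis (difference 2.13 ± 0.23). The growth cone gene Gap43 rose by 0.34 ± 0.08, with -0.07 ± 0.10 in the anterior vermis (difference 0.41 ± 0.07). The astrocyte gene Agt fell by 0.69 ± 0.09 in the anterior vermis and had -0.20 ± 0.08 in the posterior vermis (difference 0.51 ± 0.07). Over the 3 cortical regions 66 of 18114 genes had an effect that differed (5 WT and 7 SCA1 animals, animal as block), against 246 with DESeq2 and 5 without the block. By contrast of regions, 105 differed between posterior and anterior vermis, 64 with a more positive and 41 with a more negative effect in the posterior vermis, and 5 between hemisphere and anterior vermis. Between hemisphere and posterior vermis edgeR called 0 genes, with 687 at an unadjusted p under 0.05, or 3.79%, and 13 called by DESeq2. The 66 genes became 32, 13, 6, 15, 33, 11, 15, 236, 28, 23 and 116 without animals 1, 2, 3, 4, 6, 7, 8, 10, 11, 12 and 13 in turn, and 25 with Slc17a6 and Ttr as covariates, 14 of them shared.

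In the deep nuclei SCA1 effects were also set against the cortical mean within the 11 animals with all 4 regions (5 WT, 6 SCA1). Aldoc fell less in the nuclei, by a difference of 0.48 ± 0.07 (adjusted p = 0.000502). So did Ppp1r16b, a phosphatase regulator gene, whose RNA fell by 1.15 ± 0.07 in the posterior vermis and 0.41 ± 0.05 in the nuclei (difference from the cortical mean 0.58 ± 0.08, adjusted p = 0.000162). The cyclin gene Ccnd1 rose by 0.72 ± 0.09, 0.77 ± 0.10 and 0.62 ± 0.08 in the anterior vermis, posterior vermis and hemisphere and had 0.23 ± 0.09 in the nuclei (adjusted p = 0.129), with a difference of -0.47 ± 0.07. Rprm differed by -1.25 ± 0.19. Cell composition differed between these dissections. The WT mean of the Purkinje cell list was 7.65 log2 CPM in the nuclei and 8.48 in the posterior vermis, that of the myelin list 8.52 and 6.33. A smaller share of cortical RNA in the nuclei was not told apart from a different effect within cells. In all 120 of 18470 genes differed, 61 with a more positive and 59 with a more negative effect in the nuclei, and 72 without SCA1 animal 11. Other divisions of the animals into the same group sizes gave counts this large often enough that chance was not excluded for this result.

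Deep nuclei and cortex differed far more than the genotypes. In WT the oligodendrocyte and iron genes Cnp and Trf were higher in the nuclei by 1.49 ± 0.06 and 1.94 ± 0.08, the mechanosensitive channel gene Piezo2 by 2.82 ± 0.11 and the growth factor receptor gene Fgfr2 by 1.12 ± 0.05 (n = 5). In SCA1 the myelin gene Mobp was higher by 2.39 ± 0.05 and the ferritin gene Fth1 by 1.82 ± 0.04 (n = 6). In WT 10052 of 17672 genes differed, 5210 of them higher in the nuclei, and in SCA1 11797 of 17719, 6019 of them higher. At 2-fold or more 1142 were higher and 186 lower in WT, and 1280 higher and 208 lower in SCA1.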

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

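The tests of Purkinje cell ratios, scaling, nuclear tissue, animal cohort and microglial RNA in this part were chosen only after the results they concern were seen. Single libraries lay far from the others of their group in 14 of 316 groups of 5 to 7 libraries, where chance alone gives about 1 in 20, or 15.8. In SCA1 animal 13 the posterior vermis library had a mean log2 CPM of the deep nuclear neuron list of 5.02 (nearest other 3.78) and of the microglia list of 3.45 (nearest 3.23), with Scn3b at 24.3 CPM (nearest 10.4). The call of Scn3b posterior vermis RNA, a rise of 1.33 ± 0.37 (adjusted p = 0.0274), ended without any of WT animals 3, 5, 7 and 10 (adjusted p = 0.0667, 0.0669, 0.0719 and 0.0659). The same animal had the lowest zebrin-negative list mean in SCA1 anterior vermis, 6.19 (nearest 6.37), and the highest Oasl2 in SCA1 deep nuclei, 49.8 CPM (nearest 28.4).

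WT animal 10 had the highest Onecut2 among WT libraries in the posterior vermis, 9.06 CPM (nearest 5.16), and in the deep nuclei, 9.65 CPM (nearest 7.25), and the highest Gprin3 in the anterior vermis, 26.3 CPM (nearest 13.7). Other values apart from their group were Onecut2 in the posterior vermis of SCA1 animal 11 (34.1 CPM, nearest 26.6), Mirt1 in the anterior vermis of SCA1 animal 8 (11.3 CPM, nearest 7.94), Scn3b in the posterior vermis of WT animal 2 (7.16 CPM, nearest 3.73), Muc3a in the hemisphere of SCA1 animal 12 (5.20 CPM, nearest 3.13), and Col5a1 in the deep nuclei of SCA1 animal 14 (11.9 CPM, nearest 6.57). The largest library, SCA1 deep nuclei of animal 8, held 31.6 M counts (nearest 25.1).

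Genotype effects that differed between regions drew attention as well, 66 genes over the cortical regions and 120 between deep nuclei and cortex. For the 66 cortical genes a grouping by chance was argued against, with at most 4 genes in the other divisions of 60 drawn, the real one included. Only a part of the possible divisions was drawn, so chance was not excluded. For the 120 genes chance was not argued against: 6 of 60 divisions gave as many, the highest 1726, several times the real count. Why some divisions gave so many genes was not tested.

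Lower Purkinje cell RNA was weighed first. A smaller share of Purkinje cell RNA alone would lower by the same factor all genes whose RNA comes from these cells only. This was assumed for Pcp2, Calb1, Car8, Ppp1r17 and Rgs8. In the posterior vermis 9 of their 10 ratios differed between genotypes, with 7, 8 and 6 in the anterior vermis, hemisphere and deep nuclei. The ratios share genes and are not independent. In the anterior vermis none among Pcp2, Calb1 and Car8 differed (exact permutation adjusted p of at least 0.0552). RNA of these genes from other cells would also change ratios, so the test cannot decide without that assumption. Library scaling was argued against, since all 16 genes of the list were called lower in each cortical region under both other scalings. Regulation within Purkinje cells may therefore contribute beside any loss of their RNA, as a hypothesis found and tested on the same data.

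The larger difference of genotype effects between posterior and anterior vermis was weighed next. Less nuclear tissue in the SCA1 anterior vermis dissections may contribute and stays open. Over 900 genes at least 2-fold higher in nuclei, the per-animal median difference of anterior minus posterior vermis was 0.23 ± 0.12 (SD, n = 5) in WT and 0.07 ± 0.13 (SD, n = 7) in SCA1 (exact permutation p = 0.0568). Of the 66 genes 5 were nuclear, 7.58% against 5.86% of all genes (Fisher p = 0.593), and 14 of the 66 were also called with Slc17a6 and Ttr as covariates. A biological difference between the lobules was not tested apart from this.

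Higher interferon response genes were weighed last. The cohort of animals numbered 73000 and above was argued against in the cortex, where at least 86.5% of the list median was kept without them. In the deep nuclei 59.3% was kept, the median going from 1.13 to 0.67, and there a part due to this cohort cannot be told apart from genotype because these animals are all SCA1. More microglial RNA alone was argued against, since the list mean minus the microglia list mean was higher in SCA1 in each region (largest exact permutation p = 0.0139). In the posterior vermis the microglia list mean also rose, from 2.92 in WT to 3.23 log2 CPM in SCA1, so it may contribute there. Which cells held the interferon response RNA was not tested. An interferon response of the SCA1 cerebellum may underlie the cortical rise, while housing and infection were not given and stay open.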

How the results depend on the processing

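Slc17a6, Ttr and Gabra6 covariates were tests chosen only after the results were seen. Genotype effects of genes named by the rule were refitted under up to 12 alternatives, and none reversed: of 4350 values 4092 stayed on their side of the threshold, 250 fell short of it and 8 newly passed. Genes named from region and interaction tests were not followed singly. Leaving out 1 animal gave 4402, 330 and 4 of 4736.

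Requiring a 1.5-fold change left 719, 822, 719 and 359 genes in the anterior vermis, posterior vermis, hemisphere and deep nuclei, 1009 and 646 among cortical regions in WT and SCA1, 21 and 26 for the interactions with cortical region and deep nuclei, and 3226 and 3734 between nuclei and cortex in WT and SCA1, fewer by construction. Without animals numbered 73000 and above the anterior vermis gave 2015 and the deep nuclei 856, with fewer samples. Slc17a6 and Ttr as covariates gave 1494 in the anterior vermis, 2479 in the deep nuclei, 842 among WT regions and 25 for the cortical interaction. The deep nuclei gave 2123 with Gabra6 and Ttr, 2003 at a false discovery rate of 0.1, 674 with the number series as covariate and 2179 with all regions in one fit. SCA1 regions matched to 5 animals gave a median of 1656, with fewer samples. Without the animal block the paired results fell to 1546 and 1749 for regions in WT and SCA1, 5 for the cortical interaction and 38 for the nuclear one. DESeq2 gave 246 and 237 for these interactions. The cortical distance changed from -0.06 to 0.0727 without animals numbered 73000 and above, neither past the test. Of 136 list tests 71 were called with the preset correlation, 8 with an estimated one and 69 by fry. Where no construction is named, the cause was not tested.

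Leaving out each animal gave 2321 to 3398 genes in the anterior vermis, 2594 to 3419 in the posterior vermis, 2697 to 3400 in the hemisphere, and 776 to 1232 in the deep nuclei (776 without WT animal 9, 841 without WT animal 5). Regions gave 1482 to 3253 in WT (1732, 1961, 2109 and 1482 without animals 2, 3, 5 and 7) and 2075 to 5367 in SCA1 (2075, 2328 and 2510 without animals 4, 6 and 8). The cortical interaction gave 6 to 236 (32, 13, 6, 15, 33, 11, 15, 236, 28, 23 and 116 without animals 1, 2, 3, 4, 6, 7, 8, 10, 11, 12 and 13), and the nuclear one 72 to 151 (72 without animal 11). Nuclei against cortex gave 8571 to 10622 in WT and 10961 to 11538 in SCA1. The cortical distance difference ranged from -0.154 to 0.0283 (0.0219 without WT animal 3, 0.0283 without SCA1 animal 12), the nuclear one from -0.0848 to 0.184 (-0.0848 and -0.0125 without WT animals 2 and 3). With no low-count filter 2751 genes were called in the anterior vermis in place of 3237, with 31354 tested in place of 17082. What depth limits was not tested.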

Other observations

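The divisions of the anterior vermis animals and the count of calls around Atxn1 were tests chosen only after the result was seen. Heat shock and unfolded protein response genes had medians of -0.33, -0.33, -0.31 and -0.33 in the anterior vermis, posterior vermis, hemisphere and deep nuclei, with 4, 3, 3 and 2 of 17 members lower; the chaperone gene Hspb1 fell by 1.04 ± 0.17 in the posterior vermis. Camera called the list lower in the 4 regions (adjusted p = 0.434, 0.476, 0.572 and 0.497 with an estimated correlation). Camera called immediate early genes lower in the anterior vermis and deep nuclei (adjusted p = 0.0372 and 0.0101; adjusted p = 0.459 and 0.573 with an estimated correlation), where Ier2 fell by 0.79 ± 0.20 in the anterior vermis, while Jun rose by 0.68 ± 0.13 in the posterior vermis. Cholesterol synthesis genes were lower for 7 of 24 members in each region, among them Cyp51 (-0.50 ± 0.07 in the anterior vermis), and were called by camera in the anterior vermis, hemisphere and deep nuclei (adjusted p = 0.445, 0.639 and 0.275 with an estimated correlation). Perineuronal net genes were called lower in the anterior vermis (camera adjusted p = 0.0365, and adjusted p = 0.24 with an estimated correlation), where the link protein gene Hapln4 fell from 176.9 to 116.8 CPM (-0.60 ± 0.07).

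Cytosolic ribosomal protein genes were slightly higher in the posterior vermis and hemisphere (medians 0.12 in both, 5 and 15 of 42 members, and 0 and 22 adjusted over the list alone; adjusted p = 0.476 and 0.5 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were called higher in the hemisphere and deep nuclei with medians of 0.07 and 0.04 (8 and 0 of 56 members; adjusted p = 0.577 and 0.815 with an estimated correlation). Synaptic vesicle and scaffold genes were called lower by camera in the hemisphere (10 of 21 lower, 2 higher; adjusted p = 0.303 with an estimated correlation) and by fry also in the posterior vermis (adjusted p = 0.0217); Shank2 fell by 0.66 ± 0.06 in the hemisphere. Choroid plexus genes were called lower by camera in the posterior vermis (median -1.45, no member called; adjusted p = 0.542 with an estimated correlation) and in no other region. Camera called none of these lists in any region: molecular layer interneurons (smallest adjusted p = 0.101), Golgi and unipolar brush cells (0.137), oligodendrocyte precursors (0.076), endothelium (0.0678), pericytes (0.087), meninges (0.213), reactive astrocytes (0.088), mitochondrially encoded genes (0.342), Capicua targets (0.729), and neurotrophin, IGF and VEGF signalling (0.187). Fry called lower endothelium and reactive astrocyte genes in each cortical region, neurotrophin, IGF and VEGF signalling in the 4 regions, and molecular layer interneurons in the posterior vermis (adjusted p = 0.0249). It did not call heat shock genes in any region, immediate early genes in the anterior vermis or deep nuclei, ribosomal genes in the posterior vermis or hemisphere, oxidative phosphorylation in the hemisphere or deep nuclei, cholesterol synthesis in the hemisphere, choroid plexus in the posterior vermis, myelin in the hemisphere or deep nuclei, or granule cells and disease-associated microglia in the deep nuclei. Median and mean differed in sign for Capicua targets in the anterior and posterior vermis, mitochondrially encoded genes in the posterior vermis and hemisphere, oligodendrocyte precursors in the posterior vermis, meninges in the deep nuclei and molecular layer interneurons in the anterior vermis, and median and test for choroid plexus in the deep nuclei.

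Around Atxn1, 10 Mb to each side, 34 of 154, 30 of 153, 38 of 150 and 13 of 154 genes were called in the anterior vermis, posterior vermis, hemisphere and deep nuclei. Shares as large occurred in 23.3%, 48.9%, 14% and 33% of 442 windows of the same length, so calls were not unusually dense around Atxn1. A few passenger variants linked to Atxn1 could not be seen this way, since 19%, 19.6%, 20.3% and 7.52% of all genes were called. The labels also gave no mouse line.

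A grouping of the animals by chance was argued against for the genotype effect in each cortical region. The real division gave 3237 genes in the anterior vermis, 3330 in the posterior vermis and 3422 in the hemisphere. The other divisions of 100 drawn gave at most 103, 620 and 189. Only a part of the possible divisions was drawn for any result, so chance was not excluded. In the deep nuclei 2 of 100 divisions gave 1291 genes or more, the real one included. The other one gave 1363, more than the real count, so chance was argued against less firmly there. Chance was also argued against for regions in WT (3204 against 1280) and SCA1 (3910 against 1089). The same held for nuclei against cortex in WT (10052 against 8803) and SCA1 (11797 against 8898). It held as well for shared calls in the 11 animals with all regions (2612 against 1332). Each of these results had 1 of 100 divisions as large, the real one.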
